A study of Mus musculus with 10 samples.

How the data were processed

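The series holds 10 arrays of total RNA from the dental mesenchyme of the mouse lower incisor, 5 from incisors whose inferior alveolar nerve had been resected 2 weeks earlier and 5 from the contralateral incisors, taken at postnatal day 60. Per the labels, RNA was extracted with a commercial kit and labelled with biotin by the array maker's standard protocol. The deposited values are log2 intensities per probe set, 1 column per array, with no missing values and no pooled columns. RMA, which corrects background, normalizes between arrays and summarizes probes into probe sets, is named in the submitters' processing notes without a version, and no further step is given in the sources used here. Array medians near 1.5 and values below 0 are lower than this method usually gives, so a variant with a correction for GC content or a stronger background subtraction is possible; which one was used is not known, and differences between low values depend on it. The log2 scale was taken from the values, which ran from -0.16 to 13.2 with medians between 1.48 and 1.54 per array. The files give no detection calls, so a low value cannot be told from background, and differences between low values are compressed. The values were used as deposited, with no further normalization.

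The value table holds 45101 probe sets. The 64 control probe sets were left out of the tests, which left 45037. In the platform annotation supplied with the values, 34945 of these name 1 gene symbol, 932 several and 9160 none. Symbols were compared through Entrez identifiers with a RefSeq gene table, where 34741 matched and 0 symbols had to be changed. A gene is represented by its probe set with the highest mean over the 10 arrays, among probe sets with 1 symbol, which gave 18193 genes. Probe sets of a gene can disagree: of the 127 genes named in the text 74 have several probe sets, and in 56 of these every probe set had the same direction. Of the 127 genes 25 had a mean below 2.

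Denervated arrays were compared with contralateral arrays by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, gene by gene, with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05 on the adjusted p. Every signed difference is denervated minus contralateral on the log2 scale, and the errors of differences are limma's standard errors. The mouse was not a term of this fit. Whether equal sample numbers pair the arrays was checked on the data. The study's design text says that both incisors of 5 mice were used, without saying that equal numbers mark a mouse. The deviations from the group means, over genes, correlated between 0.18 and 0.57 in the 5 same-numbered pairs and between -0.41 and 0.22 in the 20 other pairs, and 4 of the 5 denervated arrays correlated best with their own number. Xist and Y-linked transcripts matched within all 5 numbers, 3 with high Xist and 2 with high Y-linked transcripts; Ddx3y, which the plan named for this, was not analysed here, and 4 sex-linked genes were used. The numbers were therefore taken to pair the samples, number 1 being mouse 1 and so on, and the fit with the mouse as a block was run beside the other. The labels do not say whether the incisors of a group were processed on different days.

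Gene lists and cell type marker lists, 40 in all, were fixed before the data were examined, with 720 of 775 members measured. Of these, 39 lists with at least 5 measured members were tested by limma's camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists; the short list of sex-linked genes served the pairing check only. Camera compares a list with the other genes. Its version with an estimated correlation, and fry, which asks whether a list's genes move on balance in a common direction, were run as alternatives. A list score, the mean over members of log2 values centred per gene, was computed per array and tested by an exact two-sided permutation of the 10 arrays (252 arrangements, smallest possible p 0.00794) and by exact sign flips of the 5 within-mouse differences (smallest possible p 0.0625).

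The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 genes of each direction with the largest difference among those past the threshold, filled by unadjusted p where fewer pass, clone names passed over. It adds up to 4 members past the threshold per list, or at most 2 with the smallest p where none passed, and a fixed set that includes Gli1, Ptch1, Hhip, Smo, Shh, Mbp, Sox10, Tubb3, Nefl, Dspp, Dmp1, Col1a1 and Mki67; some genes of the set were not analysed here. Since no gene passed, all were given without a call. Genes outside the rule are said to be chosen after their values were seen.

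The fits were tested on simulated data with the real genes' means and spreads and changed genes of known size among 18193, drawn from those with a mean above 4. Without the block 50%, 86%, 92% and 98% of genes changed by 0.5, 1, 1.5 and 2 log2 units were recovered (50 genes each), with 5 false calls. With the block 44%, 90%, 94% and 98% were recovered, with 11 false calls. All changed genes were planted at once, in noise independent between genes and with no array standing apart. These shares can therefore not be carried over to the real arrays. For lists, 5 of 5 lists of 20 genes shifted by 0.4 were recovered and 0 of 20 unshifted lists were called, in data simulated without correlation between genes. Alternatives fixed in advance were the mouse as a fixed or random block, centring of arrays on their medians, quantile normalization, leaving out the 40% of genes with the lowest mean, the mean of a gene's probe sets, every probe set on its own, eBayes with a trend and a robust prior, array weights, leaving out each array in turn, an adjusted p threshold of 0.1 and a minimum log2 difference of 1. Figures were drawn with matplotlib 3.10.9. No genome coordinates are given.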

Results

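Total RNA from the dental mesenchyme of the lower incisor was measured on 10 oligonucleotide expression arrays. The mouse incisor grows throughout life. Its mesenchyme is the pulp tissue inside the tooth, with odontoblasts, stem cells, vessels and endings of the inferior alveolar nerve, the sensory nerve of the lower jaw. In 5 wild-type C57BL/6J mice that nerve was resected on 1 side, and 2 weeks later, at postnatal day 60, the incisors of both sides were sampled. The 5 arrays of the operated side are called denervated here and the 5 of the other side contralateral. The values are log2 intensities, with array medians between 1.48 and 1.54 and highest values between 12.9 and 13.2. Pearson's correlation between arrays lay between 0.982 and 0.997 over 18193 genes, which are not independent replicates. The number of arrays limits the precision: the median standard error of a log2 difference was 0.10, and 40.7% of the genes had a mean below 2, near the low end of the scale.

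The comparison asked which transcripts differ between denervated and contralateral incisor mesenchyme. No sham-operated incisors are among the samples, so loss of the nerve cannot be told apart from the operation itself. In the denervated incisors the marker lists of macrophages and monocytes and of pericytes and smooth muscle shifted higher, with median log2 differences of 0.43 and 0.33 (n = 5 arrays per group). The cell cycle and dental mesenchyme lists shifted higher by medians of 0.18 and 0.08. The dental epithelium and osteocyte lists shifted lower, with medians of -0.34 and -0.23. Some of these calls rested on 1 array. The epithelium median was -0.01 without denervated array 3, the osteocyte median -0.09 without denervated array 2, and the cell cycle median 0.03 without contralateral array 3. The 6 lists were among 39 fixed in advance, tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of 100 splits of the 10 arrays into groups of 5, the real one included, 58 gave as many lists. All but 16 of the 126 possible splits put both incisors of at least 1 mouse on the same side. The 58 therefore also reflect differences between mice. With the mouse as a block 10 lists passed, 6 higher and 4 lower, the 6 above among them. Of the 16 splits that part all 5 mice, the real one included, 5 gave as many lists with the block. None passed with the correlation between genes estimated for each list, where the smallest adjusted p was 0.404. None passed with limma's fry, smallest adjusted p 0.135, or with an exact permutation of list scores over the 10 arrays, smallest adjusted p 0.155. That permutation cannot give a p below 0.00794, so a single list at this value could not pass the adjustment over 39 lists.

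No gene among the 18193 passed limma's test after Benjamini-Hochberg adjustment, the smallest adjusted p being 0.790. At an unadjusted p under 0.05 there were 1129 genes, 746 of them higher and 383 lower in the denervated incisors, where chance would give 909.7. With the mouse as a block 0 genes passed as well (smallest adjusted p 0.234), and 1805 genes had an unadjusted p under 0.05, 1272 higher and 533 lower. In all 5 mice 1888 genes differed in the same direction, 1197 higher and 691 lower. That is 10.4% of the genes, against 6.25% by chance for independent values. Each gene named here therefore has an adjusted p of 0.790 or above without the block, and its values are given without a call. Leaving out 1 array moved the difference of 59 of the 127 named genes by over 1.5 times, through 0 in 9 of them, and the median of 36 of the 39 lists.

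Camera with its preset correlation ranked the macrophage list first. By unadjusted p, an estimated correlation put the osteocyte list first, and fry the TGF-beta and BMP list. All 23 measured members of the macrophage list had a higher mean in the denervated incisors, 16 of them in each of the 5 mice. Camera's adjusted p was 1.06e-10 (adjusted p = 0.404 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 4 of 23 did, and 17 of 23 with the mouse as a block. Fcgr1, the high-affinity receptor for immunoglobulin G, had a log2 value of 3.56 ± 0.21 in the denervated and 2.92 ± 0.17 in the contralateral incisors (SD, n = 5), a difference of 0.64 ± 0.12 (SE). The lysozyme gene Lyz1 differed by 0.54 ± 0.16. Fcna, a lectin that activates complement, differed by 1.35 ± 0.31, and Clec4a3, a lectin receptor of myeloid cells, by 0.90 ± 0.20; both were among the 10 top genes of their direction and higher in 5 of 5 mice. Further members were chosen after their values were seen. The mannose receptor gene Mrc1 differed by 0.69 ± 0.23, Lyz2 by 0.63 ± 0.19, the complement gene C1qa by 0.50 ± 0.18, Cd68 by 0.74 ± 0.28 and the growth factor receptor gene Csf1r by 0.30 ± 0.15, each higher in 5 of 5 mice. The list score, the mean of gene-centred log2 values of an array, was higher by 0.20, 0.69, 0.90, 0.11 and 0.25 in mice 1 to 5. An exact two-sided permutation of the score over the arrays gave p = 0.0238, or 0.186 after adjustment over the 39 lists. Exact sign flips of the within-mouse differences gave p = 0.0625, the smallest possible with 5 mice. Without the denervated arrays of mice 2 and 3, which stand apart in several cell type lists, the median was 0.15 and camera's adjusted p 1.05e-05; this alternative was chosen after seeing the data.

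**Figure D1:**
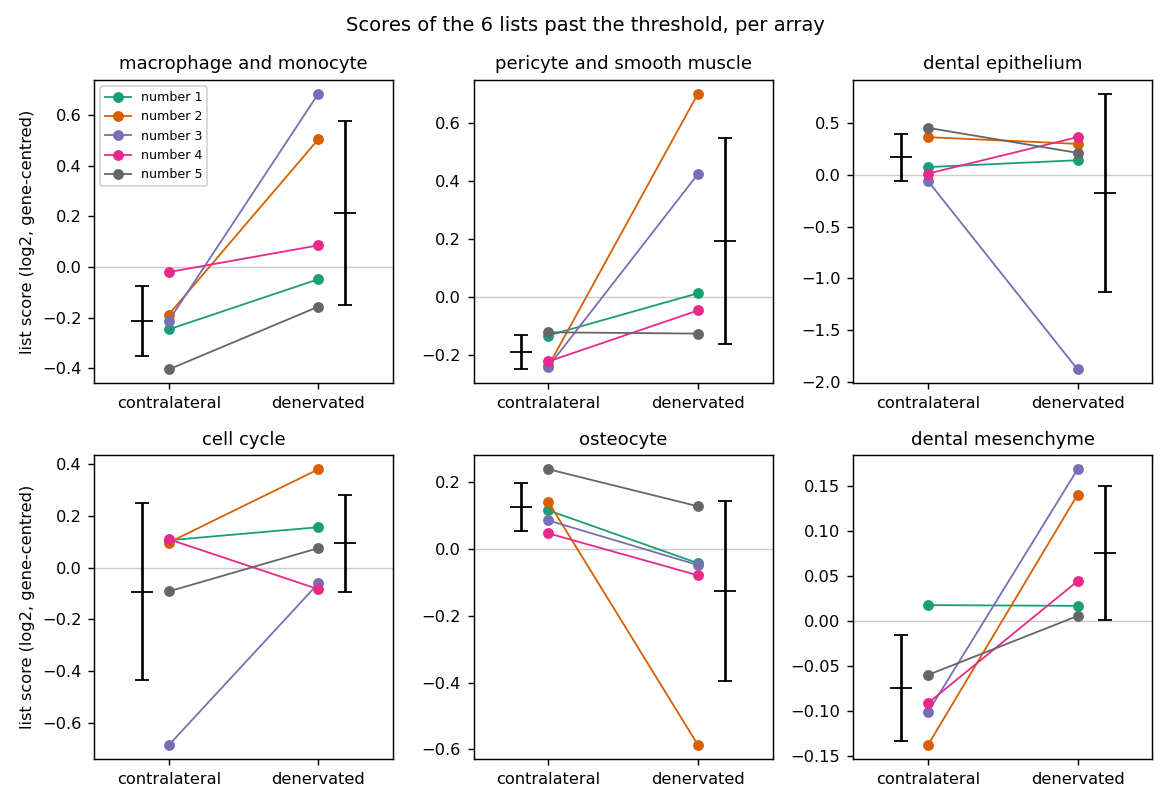
List scores per array for the 6 lists past the threshold of camera with its preset correlation; the vertical axis is the mean of gene-centred log2 values, circles are arrays, lines join both incisors of a mouse, and black bars are group means ± SD (n = 5). The macrophage score was higher in the denervated incisor of all 5 mice, whereas the shift of the dental epithelium came from mouse 3, with a difference of -1.82.

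Genes of the vessel wall were the next group. The pericyte and smooth muscle list had 15 of its 16 measured members higher on average and 8 of them in each of the 5 mice, with camera's adjusted p of 8.7e-07 (adjusted p = 0.404 with an estimated correlation). Adjusted over the list alone 3 of 16 members passed (6 with the mouse as a block), and 0 over all genes. The score was higher by 0.94 and 0.66 in mice 2 and 3 and by at most 0.18 in the others, and without the denervated arrays of mice 2 and 3 the median was 0.15 and the adjusted p 0.0157. Itga7, a laminin receptor subunit of muscle cells, differed by 0.33 ± 0.08 at a level near the low end of the scale, and Pdgfrb, the pericyte receptor for platelet-derived growth factor, had 9.73 ± 0.14 against 9.40 ± 0.17 (SD, n = 5). The smooth muscle actin gene Acta2 and the smooth muscle gene Tagln, chosen after their values were seen, differed by 0.90 ± 0.40 and 0.66 ± 0.52. Their differences were 2.27 and 2.14 in mouse 2 and 2.18 and 2.34 in mouse 3. Aoc3, an amine oxidase of the vessel wall and fat cells, was among the 10 top genes of its direction, with 3.98 ± 0.60 against 2.86 ± 0.25. Endothelial markers were higher on average in 20 of 20 members, with a median difference of 0.17 and an adjusted p of 0.0761, or 0.0416 with the mouse as a block (adjusted p = 0.83 with the block and an estimated correlation). The list also passed without denervated array 1, 4 or 5 or contralateral array 1 (adjusted p 0.0376, 0.00039, 0.0226 and 0.0303). Their score was higher by 0.62 and 0.60 in mice 2 and 3 and lower in mice 1, 4 and 5. Without the denervated arrays of mice 2 and 3 the endothelial list was lower, with a median of -0.10 and an adjusted p of 0.0487. Pecam1, an endothelial adhesion gene, differed by 0.46 ± 0.22 and the endothelial transcription factor gene Sox17 by 0.28 ± 0.20.

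Transcripts of the enamel-forming epithelium were abundant in these samples. The ameloblastin gene Ambn had 13.02 ± 0.05 and the amelogenin gene Amelx 12.87 ± 0.06 in the contralateral incisors (SD, n = 5). The dental epithelium list shifted lower, with 20 of 22 members below 0 and camera's adjusted p of 0.00066 (adjusted p = 0.83 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The score was lower by -1.82 in mouse 3, and between -0.24 and 0.35 in the others. Without denervated array 3 the median was -0.01 and the adjusted p 0.659, so that the call rested on this array. In mouse 3 Enam, which encodes enamelin, differed by -8.77, Amelx by -4.60, Ambn by -3.43, the keratin gene Krt14 by -2.12 and Shh by -1.15; these genes, apart from Shh, were chosen after their values were seen. Enam was at 0.82 there, near the low end of the scale, and Amelx and Ambn lie near its top in the other arrays, so the sizes of these 3 are lower bounds. Over all mice the enamelysin gene Mmp20 differed by -0.33 ± 0.16 and the desmoplakin gene Dsp by -0.37 ± 0.21.

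**Figure D2:**
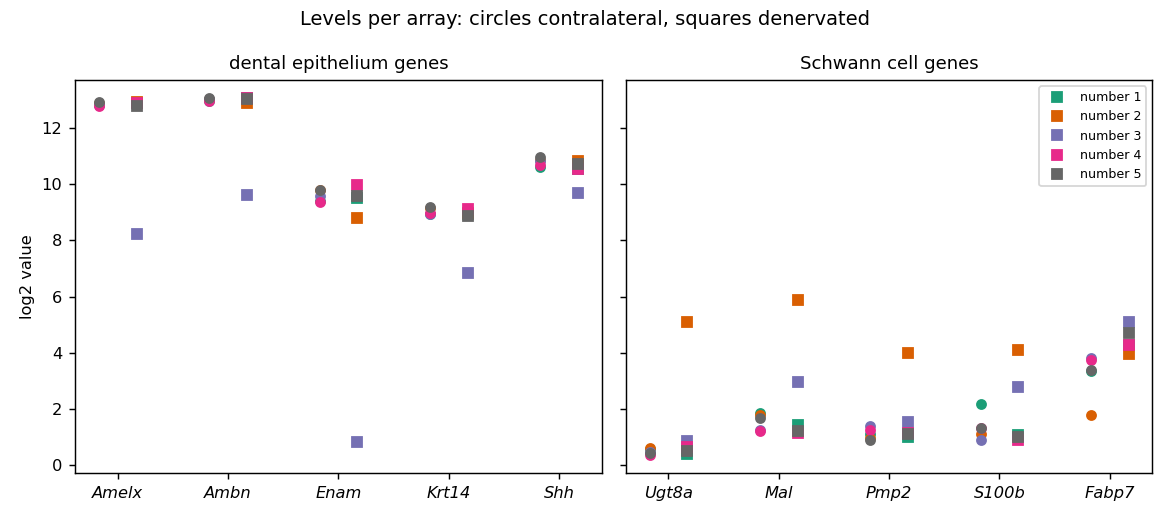
Log2 values per array of genes of the dental epithelium (left) and of Schwann cells (right), circles for contralateral and squares for denervated arrays, coloured by mouse. Denervated array 3 lies apart at the epithelial genes, with a difference of -8.77 for Enam, and denervated array 2 at the Schwann cell genes, with a difference of 4.51 for Ugt8a.

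Hedgehog signalling, in which SHH protein induces Gli1, Ptch1 and Hhip in responding mesenchyme, gave no list past the threshold. The pathway list had 11 of 18 members above and 7 below 0, with a median of 0.03, a mean of -0.01, lower in camera's test, and an adjusted p of 0.846. The target gene list had 9 of 14 members above 0, a median of 0.03 and an adjusted p of 0.563. Gli1, a marker of incisor stem cells, had 5.64 ± 0.74 in the denervated and 5.69 ± 0.46 in the contralateral incisors (SD, n = 5). Its difference was -0.04 (95% confidence interval -0.78 to 0.69), or -0.37 to 0.28 with the mouse as a block. Ptch1, the receptor gene, differed by 0.03 (-0.22 to 0.28), Smo, which encodes the signal transducer, by 0.04 (-0.13 to 0.20) and Hhip, an inhibitor gene, by 0.06 (-0.68 to 0.79). These intervals and that of Shh below are from the fit without the block. Intervals with the block are not given for them, and that of Gli1 was narrower with the block. The ligand gene Shh had a high level, 10.81 ± 0.13 contralateral, and a difference of -0.33 (-0.74 to 0.08), lower in 5 of 5 mice; without denervated array 3, which was low in epithelial genes, it was -0.14. The members with the smallest p values were Sufu, a negative regulator, at 0.29 ± 0.08 with only 1 of its 3 probe sets in this direction, Kif7 at -0.21 ± 0.12, and the forkhead genes Foxf2 at 0.41 ± 0.15 and Foxc2 at 1.07 ± 0.51. The target score was higher by 0.45 and 0.58 in mice 2 and 3, the mice with higher endothelial and smooth muscle scores, and below 0 in the others.

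Markers of the nerve itself were close to the low end of the scale, and their lists did not pass, apart from that of myelinating Schwann cells with the mean of a gene's probe sets (median 0.42, adjusted p 0.0467). For that list the adjusted p was 0.83 with an estimated correlation, from 1 probe set per gene. Only 3 of 22 axon and neuron genes and 5 of 18 genes of myelinating Schwann cells had a mean log2 value above 4. The axon list had a median of -0.07 and an adjusted p of 0.242. The neuronal tubulin gene Tubb3 had 5.69 ± 0.65 against 6.01 ± 0.35, a difference of -0.31 ± 0.28, and the neurofilament gene Nefl 0.06 ± 0.07. Prph, which encodes peripherin of sensory neurons, differed by -0.22 ± 0.11 and the synaptic vesicle gene Syt1 by 0.14 ± 0.06. The list of myelinating Schwann cells had a median of 0.41 with 12 of 18 members above 0 (adjusted p 0.356), and that of immature or repair Schwann cells 0.17 with 14 of 19 above 0 (adjusted p 0.356). Without denervated array 2 these medians were 0.06 and 0.03, and without the denervated arrays of mice 2 and 3 they were -0.06 and -0.03. Mbp, the myelin basic protein gene, differed by -0.23 ± 0.18, but only 1 of its 8 probe sets had this direction, and its difference reached 1.06 among the alternatives. The Schwann cell factor gene Sox10 differed by 0.39 ± 0.30, with 1 of 3 probe sets in this direction. The members with the smallest p values were Fabp7, a lipid-binding protein gene of immature Schwann cells, at 1.25 ± 0.36, Pou3f1, a factor of promyelinating cells, at 0.94 ± 0.49, Egr2, a regulator of myelination, at 0.42 ± 0.22, and the cadherin gene Cdh19 at 1.09 ± 0.60, each higher in 5 of 5 mice. In mouse 2 the myelinating Schwann cell score was higher by 1.53, and Ugt8a, Mal, Pmp2 and S100b, chosen after their values were seen, differed by 4.51, 4.11, 3.01 and 2.99. Ligands of neurons and growing axons had a median of -0.01 with 10 of 20 members above 0 (adjusted p 0.356); Efna5 differed by -0.33 ± 0.14 and Sema3e by -0.30 ± 0.20.

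**Figure D3:**
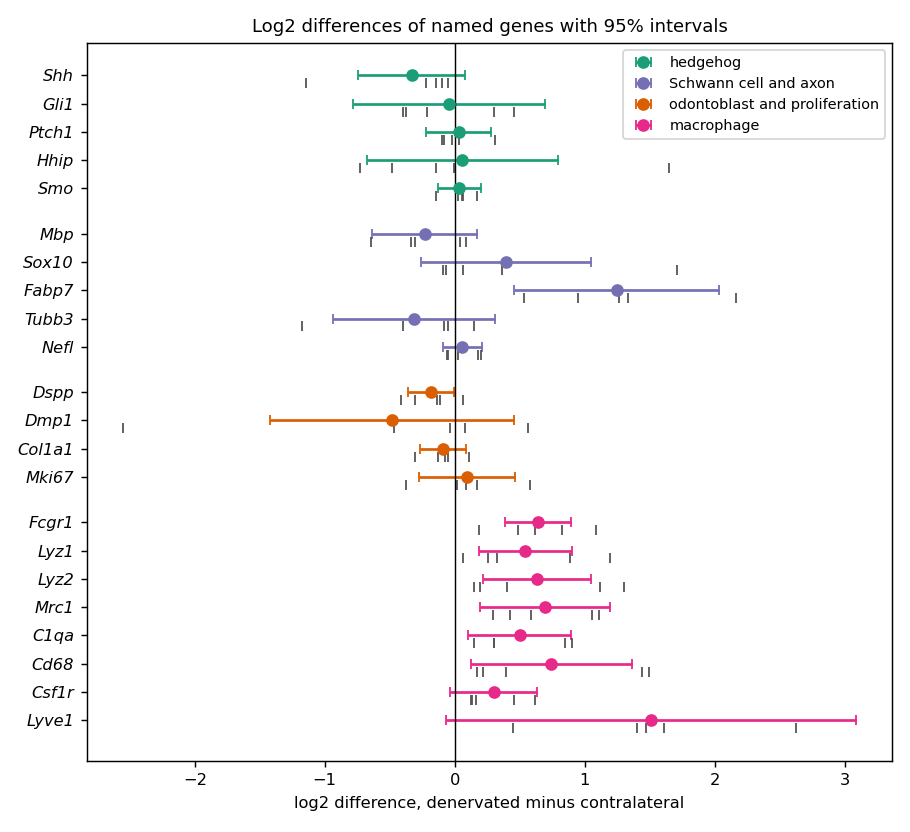
Log2 difference of named genes, denervated minus contralateral, on the horizontal axis; circles are means, bars 95% confidence intervals of limma without the block, and short ticks under each circle the differences of the 5 mice. The intervals of Gli1 (-0.78 to 0.69) and Ptch1 (-0.22 to 0.28) include 0. All 5 ticks of Fabp7 and of the macrophage genes drawn here lie above 0. Most of these macrophage genes were chosen after their values were seen, and the others and Fabp7 by a small p. Of all 23 measured members of the macrophage list, 16 were higher in each of the 5 mice. No gene passed after adjustment over all genes.

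Odontoblast genes, which make dentin matrix, stayed high in both groups. The dentin sialophosphoprotein gene Dspp had 12.07 ± 0.14 against 12.25 ± 0.08 (SD, n = 5) and Col1a1 12.98 ± 0.15 against 13.07 ± 0.05. The odontoblast list had a median of -0.09 with 11 of 17 members below 0 (adjusted p 0.0675, or 0.0440 with the mouse as a block and 0.668 with the block and an estimated correlation). It passed in 9 of 26 alternatives, with adjusted p down to 0.00664 without denervated array 3. The intermediate filament gene Nes differed by -0.35 ± 0.15 and Ccn4 by -0.41 ± 0.18. The osteocyte list shifted lower, with 9 of 10 members below 0 and an adjusted p of 0.00785 (adjusted p = 0.404 with an estimated correlation). Adjusted over the list alone 0 of 10 passed. Of its members 6 stand in other lists too, 7 had a mean above 4, and genes such as Dmp1 are made by odontoblasts as well as osteocytes. Dmp1 had 10.84 ± 1.11 against 11.33 ± 0.14, with -2.55 in mouse 2 and between -0.47 and 0.56 in the others. The Wnt inhibitor gene Dkk1 differed by -0.36 ± 0.14 and the phosphatase gene Ptprz1 by -0.60 ± 0.30. The osteocyte score was lower in 5 of 5 mice, by -0.73 in mouse 2 and by -0.16 to -0.11 in the others. Without denervated array 2 the median was -0.09 and the adjusted p 0.0846. Channels and transporters of mineralizing cells had a median of -0.09 (adjusted p 0.150) and a score lower in 5 of 5 mice. An exact permutation of that score gave p = 0.00794, the smallest possible, or 0.155 after adjustment over the lists. The sodium-calcium exchanger gene Slc8a3 differed by -0.66 ± 0.22 and Trpm8 by -0.22 ± 0.10.

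Cell cycle genes shifted higher, with 29 of 31 members above 0 and camera's adjusted p of 0.00663 (adjusted p = 0.83 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Mki67, a marker of cycling cells, differed by only 0.09 ± 0.17, the replication gene Mcm3 by 0.38 ± 0.14 and the spindle checkpoint gene Bub1 by 0.51 ± 0.25. The cell cycle score of contralateral array 3 differed by -0.74 from the mean of the 4 other contralateral arrays. Without it the median was 0.03 and the adjusted p 0.876; without denervated array 2 the median was 0.12 and the adjusted p 0.148, and without denervated array 5 they were 0.20 and 0.0539. Inhibitors of the cell cycle and p53 targets had 7 of 14 members above 0 and an adjusted p of 0.655, with Cdkn1a at -0.35 ± 0.14 and Pmaip1 at 0.26 ± 0.20.

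Transcription factors of the dental mesenchyme shifted higher by a small amount, with 14 of 18 members above 0 and an adjusted p of 0.0226 (adjusted p = 0.404 with an estimated correlation). Adjusted over the list alone 1 of 18 passed. The homeobox genes Alx1 and Prrx2 differed by 0.44 ± 0.11 and 0.56 ± 0.20. The call ended without denervated array 2 (median 0.12, adjusted p 0.0808) or contralateral array 4 (median 0.10, adjusted p 0.0596), where the median was no smaller than the 0.08 of all arrays. It also ended with array weights (median 0.08, adjusted p 0.0578), without the 40% dimmest genes (median 0.08, adjusted p 0.142, or 0.137 with the block) and without the denervated arrays of mice 2 and 3 (median 0.08, adjusted p 0.0584). Genes associated with mesenchymal stem cells had a median of 0.05 with 12 of 17 above 0 (adjusted p 0.356), and the adhesion gene Mcam of that list differed by 0.51 ± 0.18.

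Of the other signalling lists none passed. Wnt pathway genes had a median of -0.03 with 17 of 28 below 0 (adjusted p 0.151), and passed without the 40% dimmest genes (median -0.09, adjusted p 0.00752) and without contralateral array 3 (adjusted p 0.0412). With all genes and arrays the adjusted p was 0.541 with an estimated correlation. The ligand gene Wnt6, with 7.18 ± 0.18 against 7.64 ± 0.12 (SD, n = 5), was among the 10 top genes of its direction, and Dkk3 differed by 0.26 ± 0.09. TGF-beta and BMP pathway genes had a median of 0.04 with 20 of 29 above 0 (adjusted p 0.150), and their score was higher in 5 of 5 mice. An exact permutation of that score gave p = 0.00794, the smallest possible, or 0.155 after adjustment over the lists. Id2 differed by 0.22 ± 0.08 and Bmp2 by 0.25 ± 0.09. FGF pathway genes were divided evenly around 0 (9 of 18 above, adjusted p 0.655), with the receptor gene Fgfr3 at 0.55 ± 0.15 and the ligand gene Fgf9 at -0.26 ± 0.11. Notch pathway genes had a median of 0.03 (adjusted p 0.963), with the ligand gene Jag2 at -0.42 ± 0.15 and the target gene Hey1 at 0.24 ± 0.12.

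Other cells of the immune system and the blood gave lists that did not pass. Interferon response genes had a median of 0.19 with 19 of 24 above 0 (adjusted p 0.103, or 0.00305 with the mouse as a block and 0.727 with the block and an estimated correlation); their score was higher by 0.35 and 0.59 in mice 2 and 3 and by at most 0.09 in the others. Without denervated array 3 the median was 0.03 (adjusted p 0.912), and without those of mice 2 and 3 it was -0.02. The list passed without denervated array 4 or 5 or contralateral array 3 (adjusted p 0.0188, 0.00717 and 0.0182). Irf1 differed by 0.42 ± 0.18 and Oasl2 by 0.53 ± 0.25. Cytokine and chemokine genes were divided evenly (12 of 24 above 0, adjusted p 0.963), with Cxcl12 at 0.58 ± 0.18 and Ccl8 at 0.77 ± 0.28. Neutrophil genes had a median of 0.22 (adjusted p 0.356), and their score was higher by 0.65 and 1.56 in mice 2 and 3 and lower in mice 1, 4 and 5. The granule gene Camp differed by 0.58 ± 0.45 and Lcn2 by 0.30 ± 0.24, and S100a8, S100a9 and Ngp, chosen after their values were seen, by 3.63, 3.86 and 3.86 in mouse 3. Medians of the lymphocyte and erythroid lists were -0.04 and -0.02 (adjusted p 0.356 each), and that of mast cells 0.02 (adjusted p 0.756). Their members Xcl1, Jchain, Epb42, Car2, Kit and Tpsab1 differed by -0.18 ± 0.09, 1.13 ± 0.66, -0.16 ± 0.10, -0.17 ± 0.12, 0.40 ± 0.17 and 0.24 ± 0.20.

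Matrix and skeletal lists did not pass either. Fibrillar collagen and matrix genes had a median of 0.09 with 14 of 24 above 0 (adjusted p 0.559), and fibromodulin, from Fmod, had 11.66 ± 0.14 against 11.28 ± 0.22 (SD, n = 5), with tenascin C, from Tnc, at 0.26 ± 0.08. Matrix proteases and their inhibitors had a median of 0.13 (adjusted p 0.356), with Mmp11 at 0.45 ± 0.12 and Mmp16 at -0.50 ± 0.19. Chondrocyte, osteoclast, adipocyte and skeletal muscle lists had medians of 0.11, 0.03, 0.07 and -0.02 (adjusted p 0.71, 0.808, 0.563 and 0.655). In these lists Sox9 differed by 0.19 ± 0.07, Matn1 by -0.18 ± 0.07, Acp5 by 0.63 ± 0.39, Ctsk by 0.27 ± 0.18, Fabp4 by 1.13 ± 0.30, Pparg by 0.22 ± 0.11, Ttn by -0.16 ± 0.09 and Myh1 by -0.27 ± 0.19.

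Among lists of metabolism and stress, genes of the unfolded protein response had a median of -0.09 with 15 of 20 below 0 (adjusted p 0.0547, or 0.00305 with the mouse as a block and 0.580 with the block and an estimated correlation). Without denervated array 2 the median was -0.02, without contralateral array 4 -0.03, and without the denervated arrays of mice 2 and 3 0.004 (adjusted p 0.952). The list passed in 11 of 26 alternatives, among them the block, quantile normalization (median -0.12, adjusted p 0.0221), the fit without the 40% dimmest genes (adjusted p 0.00847) and that without denervated array 4 (median -0.14, adjusted p 0.000322). The score was lower in 5 of 5 mice, by -0.15 to -0.04; the endoplasmic reticulum genes Pdia4 and Hyou1 differed by -0.23 ± 0.13 and -0.25 ± 0.17. Hypoxia and glycolysis genes had a median of 0.02 (adjusted p 0.655), with Pfkl at 0.40 ± 0.11 and Bnip3 at -0.24 ± 0.08. Oxidative phosphorylation had a median of 0.05 (adjusted p 0.356), with Ndufa5 at 0.14 ± 0.07 and Sdhc at 0.20 ± 0.11. Immediate early, heat shock and circadian clock genes had medians of 0.15, 0.02 and 0.07 (adjusted p 0.563, 0.758 and 0.563). Jund differed by -0.28 ± 0.10, Atf3 by 0.21 ± 0.11, Cryab by 1.21 ± 0.72 (0.42 without denervated array 2), Hspa1a by 0.20 ± 0.26 (0.01 without denervated array 4), Hlf by 0.30 ± 0.18 and Cry2 by 0.14 ± 0.10. Median, mean and test differed in sign for the lymphocyte, hypoxia, FGF, hedgehog pathway, Notch and cytokine lists, whose shifts were all near 0.

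**Figure D4:**
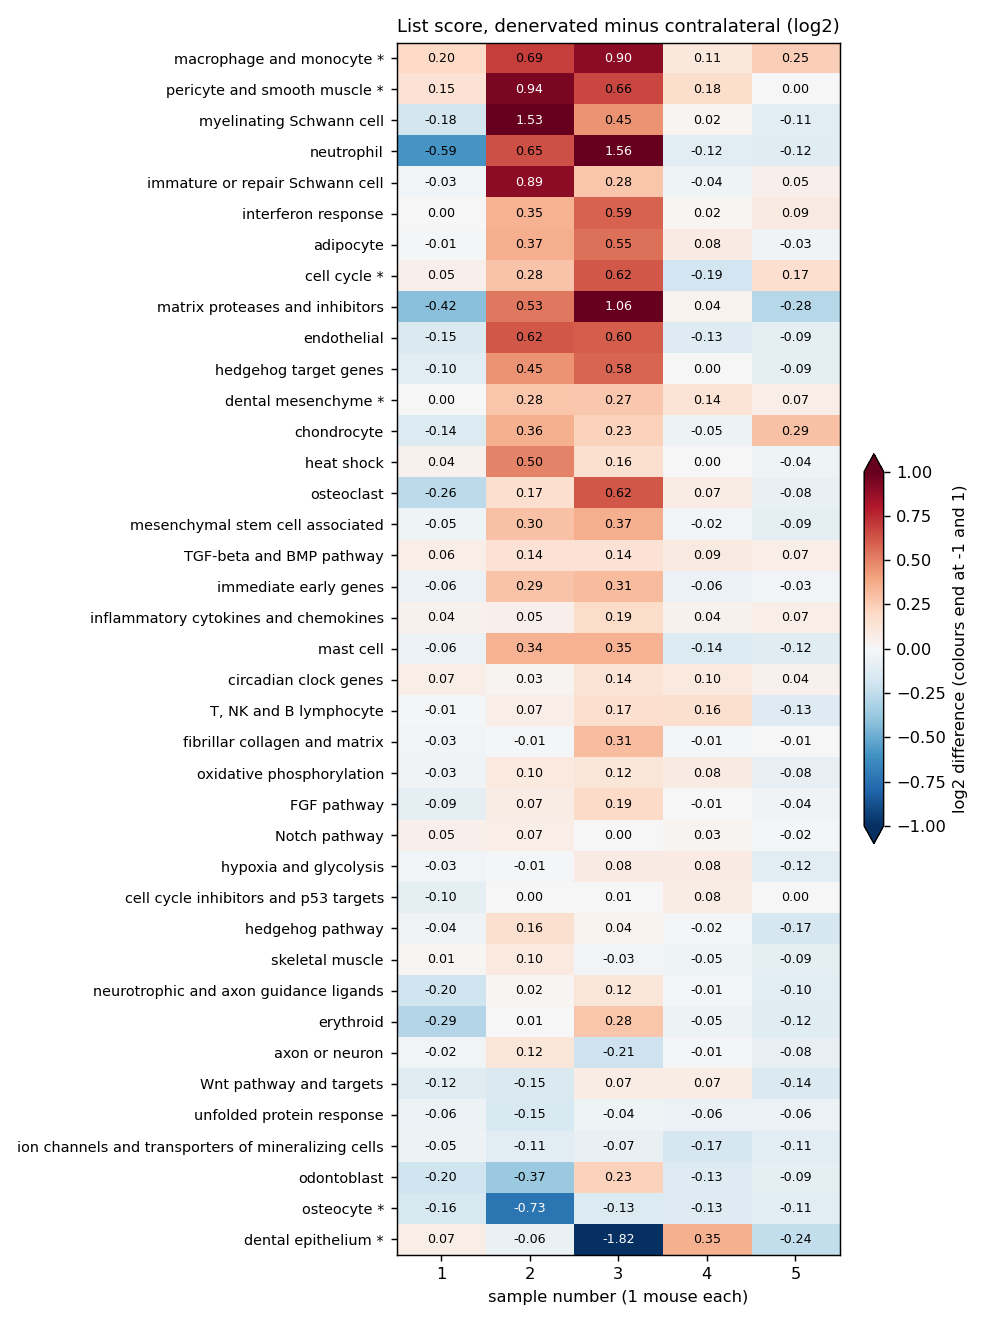
Difference of list scores, denervated minus contralateral, for the 39 lists (vertical axis, ordered by mean difference) in the 5 mice (horizontal axis); colours run from -1 to 1 log2 unit, and a star marks a list past camera's threshold with its preset correlation. Mice 2 and 3 hold most of the large differences, such as 1.53 for myelinating Schwann cells in mouse 2 and -1.82 for the dental epithelium in mouse 3.

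The remaining top genes of each direction, ranked by unadjusted p because none passed, were spread over unrelated functions. Higher in the denervated incisors were Stc2, a secreted glycoprotein gene, at 6.25 ± 0.24 against 5.37 ± 0.40 (SD, n = 5), Ifitm1, an interferon-induced membrane protein gene, at 9.84 ± 0.28 against 9.23 ± 0.16, and the lipid kinase gene Pik3c2g at 3.97 ± 0.10 against 3.44 ± 0.13. Ecrg4 differed by 0.63 ± 0.13, the inositol transporter gene Slc5a3 by 0.47 ± 0.11 and the centrosome gene Cdk5rap2 by 0.54 ± 0.12. Lower were Fat1, an atypical cadherin gene, at 9.25 ± 0.08 against 9.56 ± 0.02, and Fzd3, a Wnt receptor gene, at 6.86 ± 0.12 against 7.16 ± 0.05. Tmem151a, Diras2, Sft2d2, Ctif, Hook3, Boll and the serotonin receptor gene Htr1a differed by -0.59 ± 0.12, -0.42 ± 0.09, -0.45 ± 0.10, -0.35 ± 0.08, -0.29 ± 0.07, -0.28 ± 0.06 and -0.25 ± 0.06.

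The mice differed in how far their incisors lay apart. Over the 7919 genes with a mean above 4, the SD of the within-mouse differences was 0.19, 0.41, 0.49, 0.19 and 0.27 in mice 1 to 5, and 481 and 482 genes differed by more than 1 log2 unit in mice 2 and 3, against 16, 30 and 75 in mice 1, 4 and 5. The ratio of the 3′ to the 5′ actin control, a measure of RNA integrity, was 1.97 ± 0.12 on the log2 scale in the denervated and 2.01 ± 0.17 in the contralateral arrays (SD, n = 5; exact two-sided permutation test, p = 0.706).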

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

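Within each group of 5 arrays the gap between the farthest value and its neighbour was compared with the range of the group, for 39 list scores, 127 named genes and the actin control ratio. Of 334 such groups 35 had an array far from the other 4. Since 19 of the genes were chosen after their values were seen, several for standing apart in denervated array 2 or 3, the count is compared with chance without them: 29 of 296 groups, where 1 in 20 would be 14.8, in groups that are not independent. Denervated array 3 was the outlying array in 10 of these 29, contralateral array 3 in 5 and contralateral array 4 in 4. Denervated arrays 2 and 5 and contralateral array 2 were so in 3 each. Values below are the outlying array minus the mean of the 4 others of its group, on the log2 scale. All tests of explanations in this part were chosen after the results were seen.

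Denervated array 3 was low in transcripts of the enamel epithelium. Its dental epithelium score differed by -2.14, Enam by -8.65, Amelx by -4.66, Ambn by -3.43, Krt14 by -2.15, Dsp by -1.08 and Shh by -0.98. Enam lay near the low end of the scale there, at 0.82, and Amelx and Ambn lie near its top in the other arrays, so that these sizes are lower bounds. A drop of the same size in every mouse is argued against by the 15 epithelial genes of the list outside the enamel matrix. Their median difference was no lower than -0.165 in the 4 other mice. A smaller drop shared by the mice is not excluded. Less epithelium in that dissected piece may account for the low values of denervated array 3. The same 15 genes had a median difference of -1.31 from the contralateral array in mouse 3, 14 of them lower. These genes belong to the list that raised the question, and damage to the epithelium could lower them too, so they do not decide between the causes. A mislabelled array stays open: the sex-linked transcripts match those of the contralateral array of mouse 3, but the correlation of their deviations, 0.182, lies below the highest of the differently numbered pairs, 0.221. Damage to the epithelium of that tooth or a local effect of the operation is untested.

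Denervated array 2 stood apart in Schwann cell and osteocyte genes. Ugt8a differed by 4.52 and Pmp2 by 2.79, while the osteocyte score differed by -0.58, Ccn4 by -0.94 and the fat cell gene Fabp4 by 1.16. Degraded RNA is argued against by its actin ratio of 2.02, inside the range of the other arrays, of which the highest was 2.25. A rise of the same size in every mouse is argued against by the mean Schwann cell score difference of the 4 other mice, 0.0445 with an SD of 0.285, against 1.53 in mouse 2. A smaller shared rise is not excluded, since the array was chosen for standing apart and only 5 of the 18 genes had a mean above 4. More nerve tissue in that piece stays a candidate explanation, and it cannot be told apart from a response of Schwann cells in that incisor. The axon list had a median difference of 0.00296 there, but only 3 of its members had a mean above 4. Whether this list rises with more nerve tissue was not tested.

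Other values of denervated array 3 were the scores of cell cycle inhibitors (-0.13), collagen and matrix (0.33) and cytokines (0.26), and the genes Camp (2.51), Oasl2 (1.15), Kif7 (-0.61) and Fmod (0.31). In denervated array 5 these were the oxidative phosphorylation score (-0.14), Ecrg4 (-0.55) and Id2 (0.36). Contralateral array 3 was low in the cell cycle score (-0.74), Mki67 (-0.78), Mbp (-0.35) and Htr1a (-0.11) and high in Sema3e (0.30). In contralateral array 4 Gli1 differed by -0.98, Col1a1 by -0.11, Hspa1a by 1.07 and Slc5a3 by 0.46. In contralateral array 2 Fabp7 differed by -1.78, Camp by -0.26 and Ttn by -0.30, and in contralateral array 1 Ctsk by 0.29.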

How the results depend on the processing

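The alternatives named as added here were chosen after seeing the data, and the rest beforehand. The count of genes past the threshold was 0 under each of 23 alternatives, in both directions, with limma; at an unadjusted p under 0.05 it was 1129 and ranged from 731 to 2411, the latter over 45037 probe sets. The 127 named genes gave 2619 values under alternatives, of which 0 passed. The mouse as a block changed no other call than those of lists. It raised the lists past the threshold from 6 to 10, with 4 lower, by adding the endothelial and interferon lists (higher) and the odontoblast and unfolded protein response lists (lower). Lists lower in the denervated incisors numbered 2 and became 4 with the mean of a gene's probe sets, 5 without the 40% dimmest genes, 5 with the block and that filter (added), and 5 without denervated arrays 2 and 3 (added). In that last setting the endothelial and mast cell lists turned, with medians of -0.0998 and -0.109 (adjusted p 0.0487 each), and the epithelium, osteocyte and dental mesenchyme calls ended, while the erythroid, ion channel and odontoblast lists passed. Leaving out each array in turn gave 3 to 9 lists past the threshold, 2 to 6 higher and 1 to 5 lower; the 3 came without denervated array 2 and the 5 lower without contralateral array 3, and 4 were lower without contralateral array 2. The cause was not tested. The macrophage and pericyte calls stayed past the threshold in each of the 10, with medians of 0.33 to 0.51 and 0.25 to 0.37. Totals, higher and lower, were 0, 0 and 0 with a correlation estimated per list, with fry and with an exact permutation of scores (the permutation added). They were the same in the replicate block with an estimated correlation, with fry or with exact sign flips (each of these added). Sign flips of 5 mice cannot go below 0.0625, so that last test could not pass. Estimated correlations use the spread between arrays that is common to a list's genes, so they widen the error of lists that vary together between samples. The trend and robust prior of eBayes were not passed to camera, so the lists of that setting repeat the main result and are no check of it. Of 1002 list values, those repeats included, 915 kept direction and side of the threshold, 49 lost and 36 gained a call and 2 turned. Only the 6 lists past the threshold could lose a call, so all 49 losses fell on them. Of 26 alternatives each, the call was lost in 12 for dental mesenchyme and 9 for the cell cycle. It was lost in 8 for the dental epithelium, 8 for osteocytes, 6 for macrophages and 6 for pericytes. The lowest same-number correlation was 0.18 and lay between 0.16 and 0.23 under other scalings. Signal over background limits all low genes, 7413 of which had a mean below 2.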

Other observations

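The only test in this part whose prediction preceded the values it used is that of resident against recruited macrophage genes, together with the counts of splits for unadjusted genes and lists. Fn1, a recruited gene, is an exception, since the matrix list had already included it. The other tests were chosen after the results were seen.

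Genes that mark macrophages resting around vessels in adult tissues are of interest next to the macrophage list, although they were chosen after its result and none passed over all genes. The hyaluronan receptor gene Lyve1 differed by 1.51 ± 0.72 (SE), with 1.47, 1.40, 2.63, 0.45 and 1.61 in mice 1 to 5. A further set was written down after the list result but before its own values were looked at, except that Fn1 had already been tested within the matrix list. Its 11 measured resident genes were Folr2, at 0.79 ± 0.25, Clec10a at 0.77 ± 0.32 and F13a1 at 0.71 ± 0.40, each higher in 5 of 5 mice, Pf4 at 0.63 ± 0.25, Cbr2 at 0.49 ± 0.31, Stab1 at 0.48 ± 0.24, Mgl2 at 0.33 ± 0.17, Gas6 at 0.25 ± 0.21, Igf1 at 0.18 ± 0.19, Ccl24 at -0.03 ± 0.12 and Maf at -0.15 ± 0.23. Its 9 measured genes of recruited monocytes were Ccr2, at 0.58 ± 0.24 and higher in 5 of 5 mice, Vcan at 0.31 ± 0.19, Ifitm6 at 0.29 ± 0.15, Fn1 at 0.24 ± 0.13, Itgal at 0.22 ± 0.12, Plac8 at 0.17 ± 0.10, Hp at 0.07 ± 0.10, Ms4a4c at -0.01 ± 0.09 and Treml4 at -0.02 ± 0.09.

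Macrophage markers were higher in the denervated incisors of all 5 mice, and what is behind this was weighed. An effect of the operation itself was not tested and cannot be told apart from loss of the nerve, since no sham-operated incisors were sampled. The rise of macrophage markers was also seen outside mice 2 and 3: the mean score difference of mice 1, 4 and 5 was 0.184 and each lay above 0. The signs of 3 mice, looked at after the result was seen, cannot exclude chance there. Carried-over blood or marrow stays open: the neutrophil score was lower in 3 of 3 of mice 1, 4 and 5 and higher by at least 0.648 in mice 2 and 3, with erythroid differences of -0.29, 0.00649, 0.28, -0.05 and -0.12 in mice 1 to 5, but only 2 of 14 neutrophil and 2 of 9 erythroid genes had a mean above 4. An increase of the resident type, a hypothesis, predicted more rise in 11 resident than in 9 recruited genes in each mouse. This held in 4 of 5 mice, with 0.403 ± 0.307 against 0.205 ± 0.227 (SD). Exact sign flips of the difference gave p = 0.125, with 0.0625 the smallest possible, so the types cannot be told apart with 5 mice. Levels limit this comparison too. The recruited genes Ccr2, Hp, Ifitm6, Itgal, Ms4a4c and Treml4 had contralateral means from 0.66 to 1.84, near the low end of the scale. The resident genes Ccl24, Clec10a and Mgl2 had 1.05 to 1.78. The recruited genes Fn1 and Vcan were high, at 9.59 and 9.41, as were the resident genes Maf and Igf1, at 10.88 and 8.67. Fn1 also stands in the matrix list. Whether these genes come from macrophages in this tissue was not tested. A larger share of vessel-rich pulp stays open: the macrophage score exceeded the endothelial score by 0.255 ± 0.112 (SD) in all 5 mice, but the pericyte score by only 0.044 ± 0.210, in 3 of 5. Of the 16 splits that part all 5 pairs, 1, the real one, gave a macrophage score difference as large as 0.428, and the highest other gave 0.386. With all 5 within-mouse differences above 0 the real split had to be the largest. This count therefore repeats the sign flips of the score and is no further check, and 16 splits are too few for a share under 0.05.

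Chance could not be excluded for the counts of unadjusted genes and of lists. Of 100 splits of the 10 arrays into groups of 5 (100 of 126 drawn, the real one included), 25 gave as many genes with an unadjusted p under 0.05 as the real 1129, the highest other 3436. For lists, 58 of 100 gave as many as the real 6, the highest other 14. Most of these splits put both incisors of at least 1 mouse on the same side. Both shares therefore also carry differences between mice and do not measure chance for the side alone. For genes with an adjusted p under 0.05 the count of splits decides nothing, since the real count is 0 and all 100 must reach it; the highest other gave 56. The split with 56 and 3436 genes set both arrays of mice 1 and 2 with denervated array 3 against the rest, which points to a structure of the samples that is not the side. The next had 2577, 2146 and 2012 unadjusted genes, and each of these parted 3 of the 5 pairs. Among the 16 splits that part all 5 pairs, with the mouse as a block, 2 gave as many unadjusted genes as the real 1805 (highest other 1895) and 5 as many lists as the real 10 (highest other 12); 16 splits are too few for a share under 0.05.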
